A study of Mus musculus with 9 samples.

How the data were processed

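The data are ZEB1 CUT&RUN libraries of PB3 cells, a mouse breast cancer line labelled as lacking the oestrogen, progesterone and HER2 receptors. The 8 libraries were 2 untreated controls and 2 each after 24, 48 and 72 h in 300 nM eribulin, and 1 more library used IgG in place of the ZEB1 antibody. Per the labels, the assay was the EpiCypher CUTANA kit and libraries were sequenced paired-end at 76 bp. The labels do not say whether replicates are separate cultures, nor give a date or batch.

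The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 2.4, Bowtie2 2.2.6, Picard, MACS2 2.1.1, bedtools 2.30.0, featureCounts and deepTools with the mouse build GRCm38 (mm10), and which step used which setting is not given in the sources used here. The deposited table holds a raw count per library for each of 23623 consensus peaks, taken as integers with no scaling by the authors. The deposited peak lists, 1 per group, give for each peak a fold over the IgG library and the −log10 of its p and q. Each list is named for replicate 1 against IgG, and how replicate 2 entered the lists is not given in the sources used here. The list of consensus peaks equals the merged regions of the 4 lists, 23626 in number, less 3 regions on unplaced contigs that have no counts. The IgG library has no counts in the table and entered no test. Coverage tracks were not analysed here.

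Counts were tested with edgeR 4.0.16 in R 4.3.3. Peaks passed filterByExpr by group, which kept 21192 peaks (89.7%) and left 2431 untested, and library sizes were scaled with TMM, whose factors ran from 0.994 to 1.01. A quasi-likelihood model with 1 mean per group (robust, 4 residual degrees of freedom) gave F-tests for 24, 48 and 72 h against control, for the mean of the 3 times against control, and for 72 h against 24 h, and the 2 steps between neighbouring times were computed the same way. A peak was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested peaks. Standard errors are those of the fitted log2 fold change unless said otherwise, and CPM values are counts scaled to the TMM-adjusted library total in tested peaks. The tests, comparisons, gene lists and alternatives were chosen before the data were examined. No added control DNA was used here for scaling, so all changes are relative to the other peaks of the same library, and a change shared by every peak cannot be seen.

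Replicates were compared by a chi-square over peaks with a summed count of at least 10. The chi-square per degree of freedom was 0.931 for the controls, 0.953 for 24 h, 1.06 for 48 h and 0.965 for 72 h, where 1 is the value of 2 random draws from 1 pool. It lay between 1.12 and 2.28 for libraries of different groups. The spread between replicates is therefore close to counting error, and p-values measure only the spread between these libraries. After this was seen, a fit was added in which the pairs of control, 24 h and 72 h were each summed to 1 library, which leaves 5 libraries and 1 residual degree of freedom. That degree of freedom comes from the 48 h pair alone, which is itself close to counting error. The summed fit therefore cannot measure a spread between cultures, and calls kept in it are no independent check. A second addition thinned every library to the smallest total, 326944. DESeq2 1.42.0 (Wald test, same peaks) was an alternative planned from the start. The common biological coefficient of variation was 0.0341 in edgeR and the square root of the median dispersion was 0.259 in DESeq2. Dispersion and form of the test were not told apart as causes of DESeq2's fewer calls. The difference between replicate 1 and replicate 2, peak by peak, correlated between pairs of groups at values from -0.0302 to 0.00100. These differences are close to counting error, so values near 0 cannot tell whether replicate numbers mark a shared day. The replicate block is given as an alternative.

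Genes came from the NCBI table of assembly GRCm38.p6, with 49997 genes, of which 23128 are protein-coding or microRNA genes. It gives a start and an end but no strand, so the nearest gene boundary (start or end) took the place of the transcription start site. A peak is at a boundary when its centre lies within 1 kb of the start or end of a protein-coding gene, and otherwise inside or outside such genes. A peak was assigned to the protein-coding or microRNA gene with the nearest boundary within 50 kb, which gave 18292 peaks (77.4%) and 9855 genes. An assigned gene is a neighbour and not a shown target. No genome sequence was used here, so the planned search for the ZEB1 motif and the correction for GC content were not run.

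The 14 gene lists hold 534 members, of which 532 matched the gene table (Mx1 and Mx2 did not). They are epithelial, apical-basal polarity, mesenchymal, TGF-beta pathway, YAP and AP-1 targets, Wnt pathway, SWI/SNF, ZEB1 corepressors and chromatin, microtubule and mitosis, p53 targets and cell death, interferon and innate sensing, cytoskeleton and adhesion, ribosomal protein, and other cell types. Each list was tested with camera (limma 3.58.1) over its tested peaks with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Several peaks of 1 gene all count.

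Named peaks followed a rule fixed in advance. It takes the tested peak with the highest mean count for Zeb1, Zeb2, Cdh1, Epcam, Esrp1, Grhl2, Ovol2, Crb3, Vim and the Mir200 clusters. It takes per comparison with control the 10 called peaks with the largest rise and the 10 with the largest fall, among peaks with at least the median CPM, an assigned gene and no overlap between the libraries of the groups. It takes per list the 3 genes whose peaks have the smallest p over the mean of the 3 times, and the 5 peaks with the highest counts. A gene that the rule takes is not reported here. Genes named outside the rule are said to be chosen after their values were seen.

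Peak lists were compared with bedtools 2.31.1, where an overlap is at least 1 bp. Shares have 95% Wilson intervals, which cover counting error only, and shares of called and uncalled peaks were compared with two-sided Fisher's exact tests adjusted by Benjamini-Hochberg. Peaks are not independent replicates of the treatment, so these tests describe the peaks of these libraries. Other alternatives were scaling by total count, TMM over the peaks with the lowest counts alone, no filter, a replicate block, only the compared groups in the fit, an adjusted p of 0.1, each library left out in turn, a boundary window of 3 kb, a −log10 q of at least 5, reciprocal overlap of 50%, and boundary peaks alone for the lists. Adding peaks inside a member gene was chosen after seeing the data. Tables were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, and plots with matplotlib 3.10.9.

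The fit was tested on simulated counts drawn for 21192 peaks from their mean over all libraries, the real totals and the fitted dispersion, with 200 changed peaks. For 24 h against control it called 72.7% of peaks changed 3-fold, 37.3% of those changed 2-fold and 7.46% of those changed 1.5-fold, with 7 false calls. The same shares were 74.2, 32.8 and 8.96% at 48 h, 57.6, 35.8 and 5.97% at 72 h, 87.9, 58.2 and 13.4% for the mean of the 3 times, and 74.2, 31.3 and 1.49% for 72 h against 24 h. Most 1.5-fold changes were therefore not called in sets with 200 changed peaks. The data held more calls, which loosens the adjusted cut-off, so these shares need not hold there. The sets were drawn at the fitted dispersion, so the false calls do not measure a spread between cultures. In simulated counts for 72 h against control, camera gave p = 2.47e-12 for a list raised 1.3-fold (n = 60 peaks) and 0.684 for an unchanged list. These peaks were drawn independently of each other, so the simulation does not test whether the preset correlation suits the real lists.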

Results

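ZEB1 is a zinc-finger transcription factor that represses epithelial genes, and CUT&RUN recovers the DNA that a tethered nuclease cuts beside the antibody's target. Occupancy was measured in PB3 cells, a mouse breast cancer line, left untreated or held in 300 nM eribulin, a drug that blocks microtubule growth. There were 4 groups of 2 libraries each, an untreated control and 24, 48 and 72 h of eribulin, and 1 IgG library. The study concerns the shift of mesenchymal breast cancer cells toward an epithelial state under treatment, and the comparisons ask where ZEB1 signal changes with time in the drug. Counts in 23623 consensus peaks summed to 372896 and 672582 in the controls, 602187 and 747259 at 24 h, 765015 and 593248 at 48 h, and 441521 and 326944 at 72 h. The median count per peak lay between 10 and 24, and the highest peak held between 0.136 and 0.208% of a library. All coordinates are on GRCm38 (mm10), and each fold change below compares 2 libraries with 2, or 6 with 2 for the mean of the 3 times.

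The peak list of the untreated cells was the longest and that of the cells after 72 h the shortest. The lists, 1 per group and so without replicates, held 18749 peaks for control, 15163 for 24 h, 14479 for 48 h and 12420 for 72 h, covering 7037, 5228, 4942 and 4409 kb. The median fold over IgG was 7.14, 7.43, 8.92 and 6.82. Of the control peaks, 64.9% (95% Wilson interval 64.2 to 65.6) overlapped a peak at 24 h, 62.1% (61.4 to 62.8) at 48 h and 53.8% (53.1 to 54.5) at 72 h. In the other direction 81.2% (80.5 to 81.8), 81.2% (80.6 to 81.9) and 82.1% (81.4 to 82.7) of the peaks at 24, 48 and 72 h overlapped a control peak. The Jaccard index with control was 0.471, 0.449 and 0.400. Of the merged regions 8201 (34.7%) were in all 4 lists, 4484 (19%) in the control list alone, and 636 (2.69%) in all 3 eribulin lists but not the control list. The number of peaks in a list moves with depth and with the caller, and no test compares the lists. With a −log10 q of at least 5 the list at 48 h, with 12531 peaks, was longer than that at 24 h, with 10763, and 72 h kept 8135.

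Consensus peaks lay at gene boundaries, within 1 kb of the start or end of a protein-coding gene, in 6692 cases (28.3%), inside genes in 8540 (36.2%) and outside genes in 8389 (35.5%). Some of the best known ZEB1 targets had no consensus peak assigned. These were the splicing factor Esrp1, the transcription factors Grhl2 and Ovol2, the polarity gene Crb3, and the microRNA genes Mir200a, Mir200b, Mir429, Mir200c and Mir141. Cdh1, which encodes E-cadherin, had 4 peaks. Zeb1 itself had 3, of which 1 was tested.

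After 24 h, ZEB1 signal was higher than control at 1365 of 21192 tested peaks and lower at 976. Among peaks with an assigned gene, at least the median CPM and no overlap between the groups, the largest rises lay inside Ddah1, a gene for an enzyme that breaks down methylated arginine, at chromosome 3 145892242 to 145892775 (log2 fold change 2.4, SE 0.326, adjusted p = 3.06e-08), and inside the inositol phosphate kinase gene Ip6k3 (2.35, SE 0.316). Rises followed at the boundary of the mitochondrial ribosomal protein gene Mrps24 (2.28), near Flacc1 (2.22), at Uaca (2.13), Sfxn3 (2.09), Ssh3 (2.09), Tns3 (1.99), Otud1 (1.93) and Tmem63a (1.91). Within the same limits the largest falls were inside Hhat (-1.77, SE 0.191, adjusted p = 4.36e-12), near the cytokine signalling suppressor Socs3 (-1.59), near the collagen gene Col6a1 (-1.57), at the boundary of Klf16 (-1.54), at Alyref2 (-1.49), near the cell cycle kinase gene Wee1 (-1.49), near Rdm1 (-1.47 and -1.39), at Mir5619 (-1.44) and near Arl4d (-1.44). The Hhat, Alyref2, Arl4d and Rdm1 peaks lie within 1 kb of genes for small nuclear RNAs. Vim, the gene of the mesenchymal filament vimentin, fell at its boundary peak (-1.10, adjusted p = 1.30e-04). The median change was 1.14 among peaks that rose and -0.91 among peaks that fell. DESeq2 called 90 peaks, 61 higher and 29 lower, but not Col6a1 (adjusted p = 0.0611), Wee1 (0.0848) or Mir5619 (0.141), and with each replicate pair of control, 24 h and 72 h summed to 1 sample the count was 1892. Leaving out control replicate 2 gave 508 peaks, control replicate 1 gave 1419, and leaving out 24 h replicate 1 or 2 gave 1282 or 1059. Tmem63a (adjusted p = 0.137), Col6a1 (0.0513), Wee1 (0.0817) and Mir5619 (0.134) did not pass without control replicate 2.

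After 48 h, signal was higher than control at 1290 peaks and lower at 1147. Of the peaks with an assigned gene, at least the median CPM and no overlap between the groups, Hhat fell most (-2.67, SE 0.219, adjusted p = 3.71e-19), followed by the peak near Mreg at chromosome 1 72225923 to 72228148 (-2.25, SE 0.137, adjusted p = 7.08e-29), the peak near the mitotic kinesin gene Kif2c (-2.09), Alyref2 (-1.89), a pair of peaks at BC107364 (-1.68 and -1.57), Taf12 (-1.68), the serotonin transporter gene Slc6a4 (-1.61), Rdm1 (-1.60) and Pecr (-1.56). All of these but Slc6a4 lie within 1 kb of a small nuclear RNA gene. Among the rises were peaks inside Otud7b (2.41, SE 0.343, adjusted p = 9.98e-08), Ip6k3 (2.3), Borcs5 (2.22) and Uaca (2.11). Tmem63a (2.1), Kctd3 (2.1), Tmem221 (2.08), Mier2 (2.07), Ddah1 (2.02) and the vitamin D receptor gene Vdr (1.91) completed the 10 within these limits. DESeq2 called 76 peaks, 36 higher and 40 lower, but not Vdr (adjusted p = 0.101), and 2090 were called with summed pairs. The count was 517 without control replicate 2 and 1500 without control replicate 1, while leaving out 48 h replicate 1 or 2 gave 1263 or 1497. Tmem63a, Tmem221 and Vdr no longer passed when control replicate 2 was left out, with adjusted p = 0.0669, 0.0711 and 0.252.

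The longest treatment gave the most calls, with 1450 peaks higher than control at 72 h and 1216 lower. With the naming limited as before to peaks with an assigned gene, at least the median CPM and no overlap, Tmem63a, at chromosome 1 180942155 to 180942711, rose most (2.70, SE 0.357, adjusted p = 1.12e-08), then Ip6k3 (2.59), Vdr (2.39), Mrps24 (2.37), Serf1 (2.33), Uaca (2.27), Ankrd12 (2.18), Tmem221 (2.17), Mier2 (2.08) and 2300009A05Rik (2.04). Within these limits Hhat fell most (-3.12, SE 0.284, adjusted p = 2.97e-16). Falls followed near Plscr5 (-2.52), Mreg (-2.21), Pecr (-2.09), at Add2 (-1.99), near the stress response gene Ier3 (-1.96), Lekr1 (-1.94), Nrep (-1.94), Kif2c (-1.93) and Ano1 (-1.89). Of these, the Hhat, Mreg, Pecr and Kif2c peaks lie beside small nuclear RNA genes. The single tested peak assigned to Epcam, an epithelial adhesion gene, starts at chromosome 17 87609778 and has its centre outside the gene. It fell (-1.32, adjusted p = 0.0283), and its controls held 41.3 and 39.7 CPM against 18.5 and 12.5 at 72 h. The median change was 1.24 among the rises and -1.17 among the falls. DESeq2 called 115 peaks, 62 higher and 53 lower, but not Ier3 (adjusted p = 0.0635) or Nrep (0.0674), and 2200 were called with summed pairs. The count fell to 713 without control replicate 2, and leaving out 72 h replicate 1 or 2 gave 938 or 1310. Vdr (adjusted p = 0.0531) and Tmem221 (0.0580) did not pass without control replicate 2.

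Over the mean of the 3 times, the comparison with the most libraries, 1752 peaks rose and 1807 fell. At Ip6k3, chromosome 17 27160768 to 27161352, signal went from 11.0 and 18.3 CPM in the controls to between 73.6 and 100.4 CPM in the 6 treated libraries, a log2 fold change of 2.41 (SE 0.281, adjusted p = 3.46e-11). Tmem63a (2.24), Uaca (2.17), Ddah1 (2.13), Mrps24 (2.12), Tmem221 (2.02), Borcs5 (1.99), Mier2 (1.98), Vdr (1.95) and Serf1 (1.92) rose with it. At Hhat, chromosome 1 192745529 to 192746775, signal went from 173 and 194 CPM to between 19.8 and 64.8 CPM, a log2 fold change of -2.52 (SE 0.177, adjusted p = 4.15e-24). The fall at Alyref2, chromosome 1 171501297 to 171503835, was -1.75 (SE 0.101, adjusted p = 6.05e-31), and further large falls were at Mreg (-1.88), Kif2c (-1.69), Pecr (-1.57), Rdm1 (-1.52 and -1.49), Socs3 (-1.47), Slc6a4 (-1.45) and BC107364 (-1.40). Over all comparisons with control the rule named 24 falling peaks, of which 12 lie within 1 kb of a small nuclear RNA gene, and 19 rising peaks, of which none does. DESeq2 called 231 peaks, 121 higher and 110 lower, among them all 20 named here, and summed pairs gave 3106. The count was 663 without control replicate 2, where Tmem221 (adjusted p = 0.0618) and Vdr (0.181) did not pass, and 2021 without control replicate 1.

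**Figure D1:**
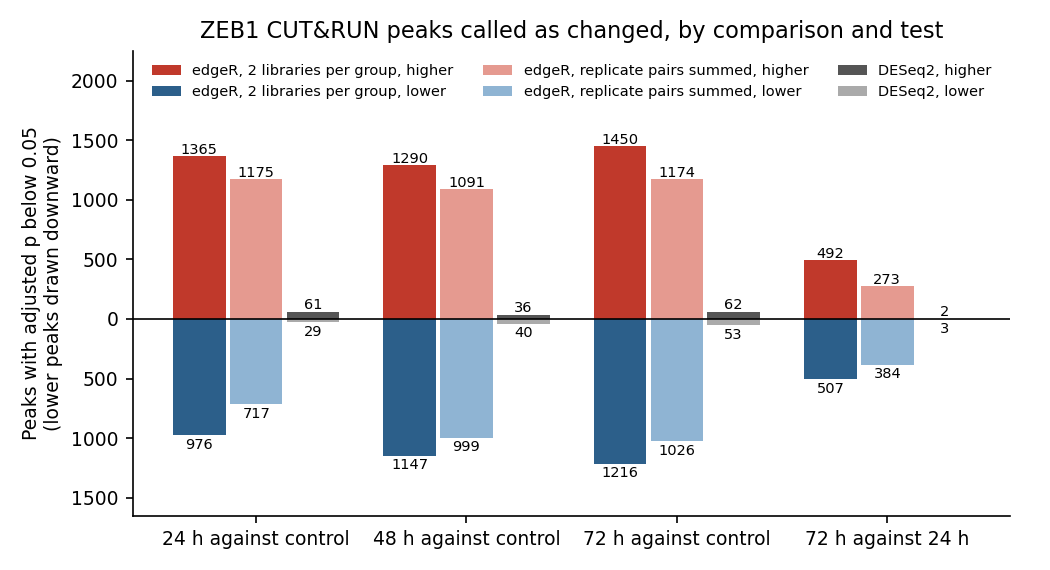
Number of peaks called higher (up) and lower (down) in each comparison by edgeR, by edgeR with replicate pairs summed, and by DESeq2, out of 21192 tested peaks. The mean of the 3 times has 3559 calls by edgeR, 3106 with summed pairs and 231 by DESeq2.

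**Figure D2:**
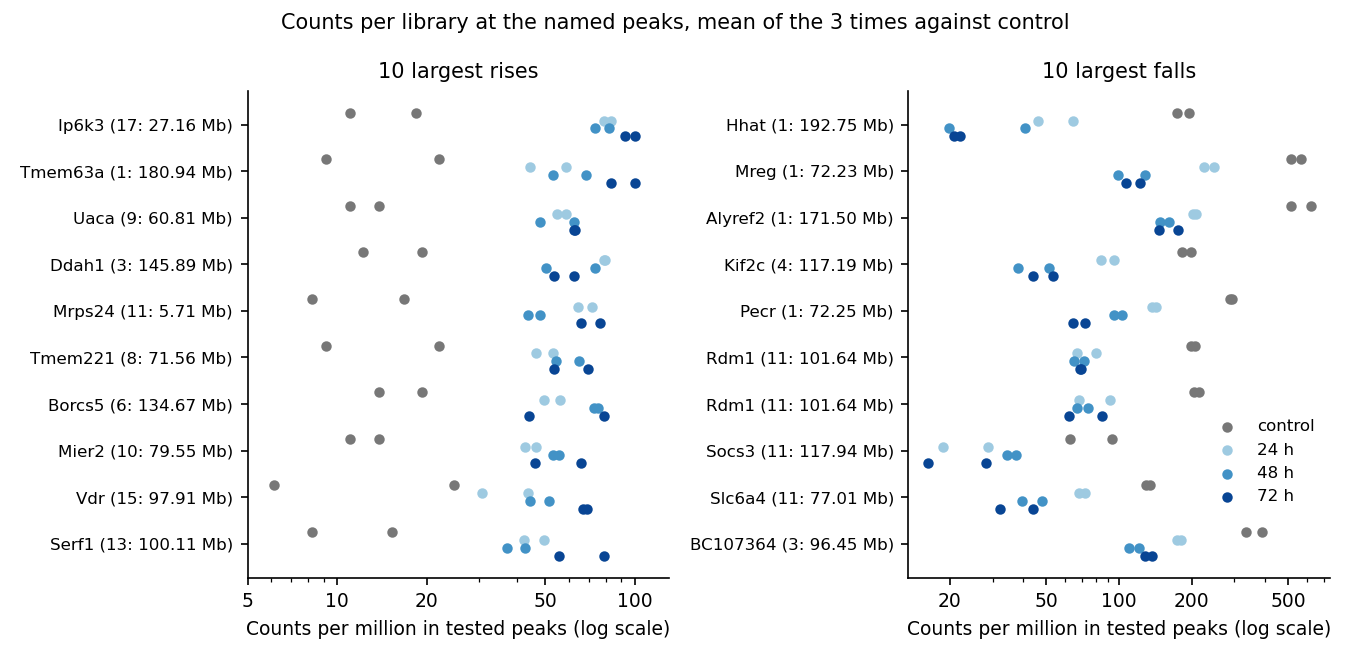
CPM in tested peaks, on a log axis, for each library (points, 2 per group) at the 10 peaks with the largest rise and the 10 with the largest fall over the mean of the 3 times, among peaks with an assigned gene, at least the median CPM and no overlap between the groups. At Hhat the controls lie at 173 and 194 CPM and every treated library at 64.8 CPM or less.

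The times shared many of their calls. At all 3 times 373 peaks were higher than control and 316 lower, out of 4850 called at any time. Rises common to 24 and 48 h numbered 645, to 24 and 72 h 497, and to 48 and 72 h 648, where independent calls would give 83.1, 93.4 and 88.3. Falls in common numbered 482, 402 and 608, where independent calls would give 52.8, 56.0 and 65.8, and 1 peak had opposite calls at 24 and 72 h. Each comparison uses the same control libraries, which alone gave correlated fold changes in 20 simulated sets without any change. The simulated correlations were 0.571, 0.484 and 0.486 and the measured ones 0.756, 0.629 and 0.778, and the covariance exceeded the simulated one by 0.217, 0.209 and 0.282. No simulated set had calls in common, but with on average 0.1, 0 and 0.05 calls at 24, 48 and 72 h the sets could hardly share any. A split chosen after seeing the data gave each comparison of a pair a different control library. The correlations were then 0.474, 0.386 and 0.518 or, with the libraries swapped, 0.477, 0.402 and 0.535. Counting error of 1 shared control library is therefore not the whole of it. The peaks were, however, called in these same libraries, with 4484 merged regions in the control list alone. Peaks picked for high control counts could fall at every time. Neither the simulated sets nor the split covers that choice. A difference from the treated libraries that both controls share for another reason would remain after the split and is not excluded.

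Peaks near mesenchymal genes were lower, as a group, than other peaks in the test with a preset correlation but not in that with an estimated one. Over the mean of the 3 times 21 of the 116 peaks near 36 genes of the mesenchymal list fell, 1 rose and 94 did not pass (adjusted over the list alone, 23 fell and 1 rose). The peak near Col6a2 fell by 2.80 on the log2 scale (SE 0.391, adjusted p = 3.73e-08), and at 72 h it held 0 and 3.14 CPM, so its size at that time is uncertain. The peak near Col6a1 at chromosome 10 76668933 fell by 1.24 (SE 0.220), the peak inside the matrix crosslinking enzyme gene Loxl2 by 1.28 (SE 0.267), and the boundary peak of Vim, chromosome 2 13573568 to 13574543, by 0.69 (SE 0.168, adjusted p = 0.00188). Chosen after their values were seen, peaks of the adhesion receptor gene Cd44 (-1.89, -0.60 and -0.52) and of Snai1, a repressor of E-cadherin, (-1.77) also fell, and Snai2 (0.70) rose. Camera with the preset correlation gave the list adjusted p = 0.00258 for the mean, with a median of -0.27, and 0.0736, 0.00159 and 0.00872 at 24, 48 and 72 h, with 14, 16 and 11 falls against 2, 0 and 3 rises. With an estimated correlation the adjusted p was 0.414 for the mean, 0.779 at 24 h, 0.493 at 48 h and 0.243 at 72 h. The list of other cell types, not expected to be active here, had a lower median at 72 h (-0.60) without passing (adjusted p = 0.0631), so a fall shared with such genes is not excluded. DESeq2 did not call Loxl2 (0.157) and gave no adjusted p for Col6a2. Without control replicate 2 the list's adjusted p was 0.234 for the mean, 0.141 at 48 h and 0.159 at 72 h, and Col6a1 (0.0926), Loxl2 (0.214) and Vim (0.152) did not pass.

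Epithelial genes moved in both directions. Of the 55 peaks near 24 genes of the epithelial list, 9 rose, 8 fell and 38 did not pass over the mean of the 3 times (11 and 8 adjusted over the list alone), and camera gave adjusted p = 0.942. Peaks of the simple epithelial keratins fell, with -0.98 (SE 0.157, adjusted p = 1.64e-06) near Krt18 and -0.71 (SE 0.138) at the Krt8 boundary, while the boundary of the protease inhibitor gene Spint2 rose by 1.46 (SE 0.337, adjusted p = 0.00105). The tight junction genes Cgn (0.73 and 1.02), Cldn3 (0.69) and Cldn4 (0.80), chosen after their values were seen, also rose. The Cdh1 peak with the highest count changed by 0.07 (SE 0.176, adjusted p = 0.826), that of Epcam by -0.51 (SE 0.276, adjusted p = 0.212), that of Zeb1 by -0.40 (SE 0.184, adjusted p = 0.115, or -0.72 and 0.0289 with thinned libraries) and that of Zeb2 by -0.28 (SE 0.192, adjusted p = 0.320). In the apical-basal polarity list 4 of 16 peaks rose and none of them fell, among them the boundary peaks of Llgl1 (1.35, SE 0.328), Patj (1.34) and Llgl2 (0.76). The polarity list's median was 0.48, with camera adjusted p = 0.164 for the mean and 0.0704 at 72 h, so the list as a group did not pass in camera. Fry called it at 72 h (adjusted p = 0.0330). Its boundary peaks were higher than other boundary peaks at 24 h (camera adjusted p = 0.0400) but did not pass at 48 h (0.183) or 72 h (0.163). DESeq2 called Krt18 (adjusted p = 0.0187) and Krt8 (0.0425) but not Vim (0.174), Spint2 (0.118), Llgl1 (0.143), Patj (0.151) or Llgl2 (0.165). Patj (0.0502) and Llgl2 (0.0779) did not pass in edgeR without control replicate 2.

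Signalling genes split in both directions within each list, and no such list passed as a group. For YAP and AP-1 targets 9 of 138 peaks rose and 12 fell (adjusted p = 0.937). The peak near the Hippo pathway gene Amotl2 rose (1.99, SE 0.382), and peaks at the boundary of Jun (-0.76, SE 0.154), an AP-1 subunit gene, and near Ier3 (-1.17, SE 0.244) fell. For the Wnt pathway 2 of 58 rose and 8 fell (adjusted p = 0.860), with a rise at the boundary of the co-receptor gene Lrp5 (1.40) and falls near Tcf7l2 (-1.19) and Wnt11 (-1.92). For the TGF-beta pathway 4 of 79 rose and 7 fell (adjusted p = 0.863), with a rise near the inhibitory Smad7 (1.24) and falls in Smurf1 (-0.71) and near Tgfbr3 (-0.68). For interferon and innate sensing 3 of 29 rose and 3 fell (adjusted p = 0.863), with Bst2 (0.95) higher and Ccl5 (-0.89) and Irf1 (-0.97) lower. Of the peaks named here DESeq2 called that near Amotl2 (adjusted p = 0.0436) and none of the others, whose adjusted p lay between 0.0652 (Jun) and 0.214 (Smad7), with none given for Wnt11. Adjusted over the list alone these lists had 9 and 12, 2 and 8, 4 and 7, and 3 and 3 calls. The medians of the YAP and AP-1 targets (0.02) and of the SWI/SNF list (-0.01) over the mean of the 3 times have the opposite sign to their camera direction. Without control replicate 2, the calls near Amotl2, Ier3, Lrp5, Tcf7l2, Smad7, Smurf1, Tgfbr3, Bst2 and Ccl5 were lost, with adjusted p between 0.0659 and 0.273, and without control replicate 1 those of Smad7 (0.0534), Wnt11 (0.0570), Bst2 (0.0684) and Irf1 (0.0829).

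The lists of cell division, cell death, the cytoskeleton, SWI/SNF and other cell types did not pass as groups in camera. Fry called other cell types, falling, over the mean (adjusted p = 0.0295). At 72 h against control it called all but the cytoskeleton, with adjusted p between 0.0282 and 0.0371. Between 72 and 24 h it called all of them, with adjusted p between 0.00908 and 0.0462. The list values below are those of camera over the mean of the 3 times. For microtubule and mitosis, the process eribulin blocks, 2 of 45 peaks rose and 1 fell (adjusted p = 0.693), namely Map1a (0.99) and Kif18a (0.86) higher and Kif2c (-1.69) lower, the last beside a small nuclear RNA gene. For p53 targets and cell death 7 of 73 rose and 3 fell (adjusted p = 0.860), with Bcl2l1 (1.40), which encodes a survival factor, higher and the death gene Bmf (-1.90) lower. For cytoskeleton and adhesion 8 of 146 rose and 15 fell (adjusted p = 0.860), with the myosin gene Myh9 (0.84, SE 0.140, adjusted p = 4.51e-06) and Rock2 (1.25) higher and Ezr (-1.15) lower, all 3 also called by DESeq2, as was Kif2c. For SWI/SNF 3 of 29 rose, Dpf1 (1.74), Phf10 (1.51) and Arid1a (1.36), and none of them fell (adjusted p = 0.863). For other cell types, markers of blood, endothelial and further cells, 4 of 14 peaks fell and none of them rose (adjusted p = 0.164), with the blood cell gene Ptprc (-1.54) and the endothelial genes Pecam1 (-0.92) and Tek (-1.02) among them. DESeq2 did not call Map1a (adjusted p = 0.280), Kif18a (0.378) or Bcl2l1 (0.124) and gave no adjusted p for Bmf, Dpf1, Phf10, Arid1a, Ptprc, Pecam1 and Tek. Adjusted over the list alone the counts higher and lower were 1 and 1, 6 and 3, 8 and 14, 3 and 0, and 0 and 4. When control replicate 2 was left out, Kif18a, Bmf, Dpf1, Phf10, Arid1a, Ptprc, Pecam1 and Tek did not pass, with adjusted p between 0.0911 and 0.252. Map1a (0.239), Bcl2l1 (0.0585), Phf10 (0.0595), Arid1a (0.158) and Pecam1 (0.0801) did not pass without control replicate 1, and Map1a (0.103) did not without 72 h replicate 1. The calls of Kif18a and Tek were each lost when any of 5 single libraries was left out.

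The ZEB1 corepressors and chromatin list passed against control at 72 h alone, and only with the preset correlation or fry. At 72 h 8 of its 49 peaks near 30 genes were higher than control and 0 lower (12 and 1 adjusted over the list alone), with a median of 0.36 and adjusted p = 0.0246, or 0.243 with an estimated correlation. The DNA methyltransferase gene Dnmt3b rose by 2.27 (adjusted p = 0.00478) and the CoREST gene Rcor3 by 1.11 (adjusted p = 0.0264). Chosen after their values were seen, Ctbp1 (1.70), Hdac1 (0.98), Hdac3 (1.10) and Ezh2 (1.5), genes of corepressors and of a histone methyltransferase, rose as well. Over the mean of the 3 times 6 rose and 1 fell (adjusted p = 0.662), though Dnmt3b (1.95), Tet3 (1.33) and Rcor3 (1.01) did not pass without control replicate 2 (0.0505, 0.123 and 0.430), and at 24 and 48 h the adjusted p was 0.831 and 0.673. DESeq2 did not call Tet3 (0.166) or Rcor3 (0.255) over the mean and gave no adjusted p for Dnmt3b. At 72 h the adjusted p of the list was 0.159 without control replicate 2 and 0.0868 with peaks inside member genes added. Of the list's peaks 53.1% lie at gene boundaries, and at 72 h against control the camera adjusted p was 0.662 for its boundary peaks against other boundary peaks and 0.275 among the rest.

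**Figure D3:**
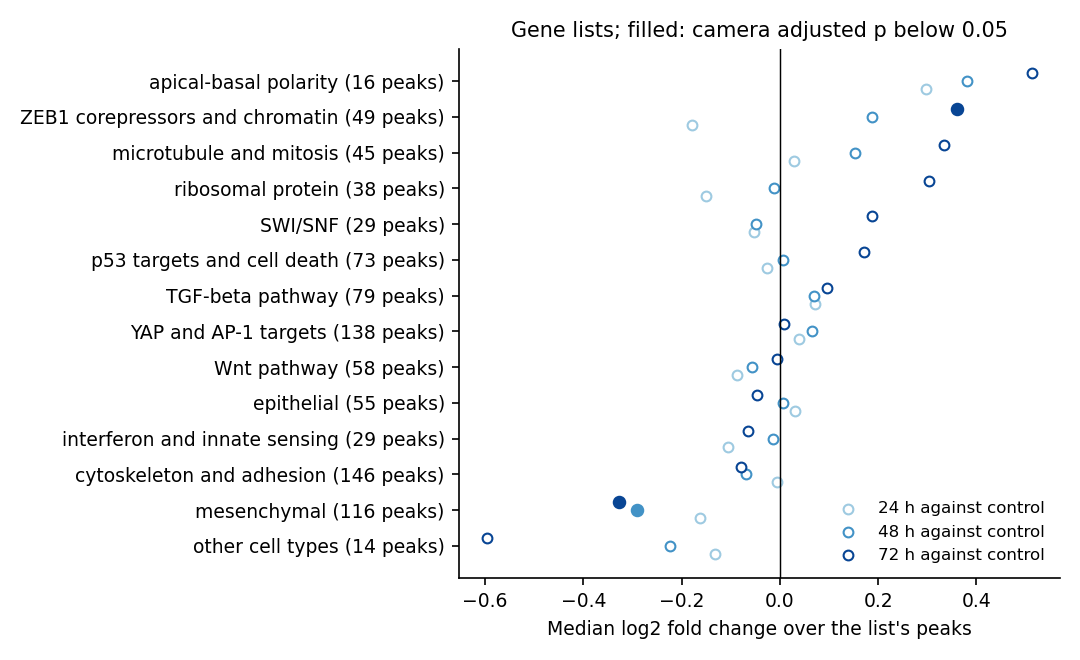
Median log2 fold change over the peaks of each gene list (points) for each comparison, with the number of tested peaks per list and filled points where the camera adjusted p was below 0.05. The mesenchymal list lies at -0.29 at 48 h and -0.33 at 72 h, and the ZEB1 corepressors and chromatin list at 0.36 at 72 h.

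Between 24 and 72 h of treatment signal shifted further toward gene boundaries. At 72 h 492 peaks were higher than at 24 h and 507 lower, and 348 of those higher (70.7%, Wilson interval 66.6 to 74.6) lay at a gene boundary against 16 of those lower (3.16%, 1.95 to 5.06) and 28.1% of uncalled peaks (Fisher's exact adjusted p = 2.09e-82 and 2.49e-48). The other lower peaks lay inside genes in 215 cases (42.4%) and outside genes in 275 (54.2%). Vim, lower than control at 24 h, was higher at 72 h than at 24 h (0.79, adjusted p = 0.0408), and Tmem63a rose further (0.79). Hhat (-1.35), Mreg (-1.02), Kif2c (-0.86), Ier3 (-1.50) and Epcam (-1.42, SE 0.401, adjusted p = 0.0240) were lower at 72 h than at 24 h. Apart from Vim and Epcam, the peaks above were named for large changes against control, so part of these differences can follow from that choice. Chosen after their values were seen, peaks of Krt18 (-0.83, -0.72 and -0.60) and Krt8 (-0.67) fell, and boundary peaks of the immediate early genes Junb (1.34) and Fos (0.81) rose. DESeq2 called 5 peaks, 2 higher and 3 lower, summed pairs gave 273 and 384, and the step from 24 to 48 h had 47 and 113 calls and that from 48 to 72 h 6 and 2. DESeq2 called none in either step, with 419 and 319 peaks at an unadjusted p below 0.05 against 3082 and 2045 in edgeR, and summed pairs gave 23 and 75, and 1 and 2. Leaving out 24 h replicate 1 or 2 gave 368 or 394 peaks between 72 and 24 h, and leaving out 72 h replicate 1 or 2 gave 280 or 208.

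Chromatin and ribosomal protein genes rose as groups between 24 and 72 h in the test with a preset correlation. In the ZEB1 corepressors and chromatin list 7 of 49 peaks rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.40 and adjusted p = 2.28e-04, or 0.121 with an estimated correlation. The rises, named after their values were seen, were at Ctbp2 (1.36), Ezh2 (1.20), Hdac1 (1.06), Kdm6b (0.89 and 0.85), Kmt2c (2.42) and Tet3 (1.55). In the ribosomal protein list 2 of 38 rose, Rpl24 (0.96) and Rps14 (0.96), and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.38 and adjusted p = 0.0105, or 0.144 with an estimated correlation and 0.205 with libraries thinned to the smallest total. Over the mean of the 3 times the ribosomal list had 1 rise near Rpl11 (1.39) and 1 fall near Rpl3 (-0.64) and adjusted p = 0.863, and Rps12 (-0.77) did not pass (adjusted p = 0.0659). Boundary peaks made up 63.2% of the ribosomal list. When boundary peaks of a list were compared with other boundary peaks only, the adjusted p was 0.552 for ribosomal genes and 0.175 for corepressors, and among peaks away from boundaries it was 0.403 and 0.0336. No other list passed in camera against all peaks in this comparison, the lowest being SWI/SNF at adjusted p = 0.0836. The epithelial list had 6 falls and 0 rises (adjusted p = 0.170), and its 10 boundary peaks as a set were lower than other boundary peaks with the preset correlation (adjusted p = 0.0122). At 24 h against control that set had been higher than other boundary peaks (0.0400), and at 72 h against control it did not pass (0.920). Rpl3 did not pass without control replicate 1 (adjusted p = 0.402) or 72 h replicate 1 (0.0677), and Rpl11 (0.0808) did not without control replicate 2. DESeq2 called neither (0.280 for Rpl3 and 0.151 for Rpl11).

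Position relative to genes set apart the peaks that rose from those that fell, more so with time. Of the peaks higher than control 27.6% (Wilson interval 25.3 to 30.1) lay at a gene boundary at 24 h, 39.1% (36.5 to 41.8) at 48 h and 59.1% (56.6 to 61.6) at 72 h, against 28.9, 28.9 and 27.6% of uncalled peaks (Fisher's exact adjusted p = 0.332, 5.00e-14 and 1.15e-125). Of the lower peaks 20.5% (18.1 to 23.1), 8.98% (7.46 to 10.8) and 4.61% (3.56 to 5.93) did (8.52e-09, 6.78e-58 and 8.39e-92). The median log2 fold change of all boundary peaks was 0.06, 0.20 and 0.37 at the 3 times, that of peaks outside genes -0.07, -0.12 and -0.22, and that of peaks inside genes 0.01, -0.03 and -0.09. As a share of all counts, boundary peaks held 27.7 and 27.5% in the controls, 27.7 and 28.4% at 24 h, 31.5 and 29.8% at 48 h, and 33.8 and 34.7% at 72 h. Among DESeq2's fewer calls the share of rises at boundaries was 24.6% (15.5 to 36.7) at 24 h, 25% at 48 h and 40.3% (29.0 to 52.7) at 72 h. There the shares of rises at 48 h and of falls at 24 h turned direction, and that of rises at 72 h lost its call.

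**Figure D4:**
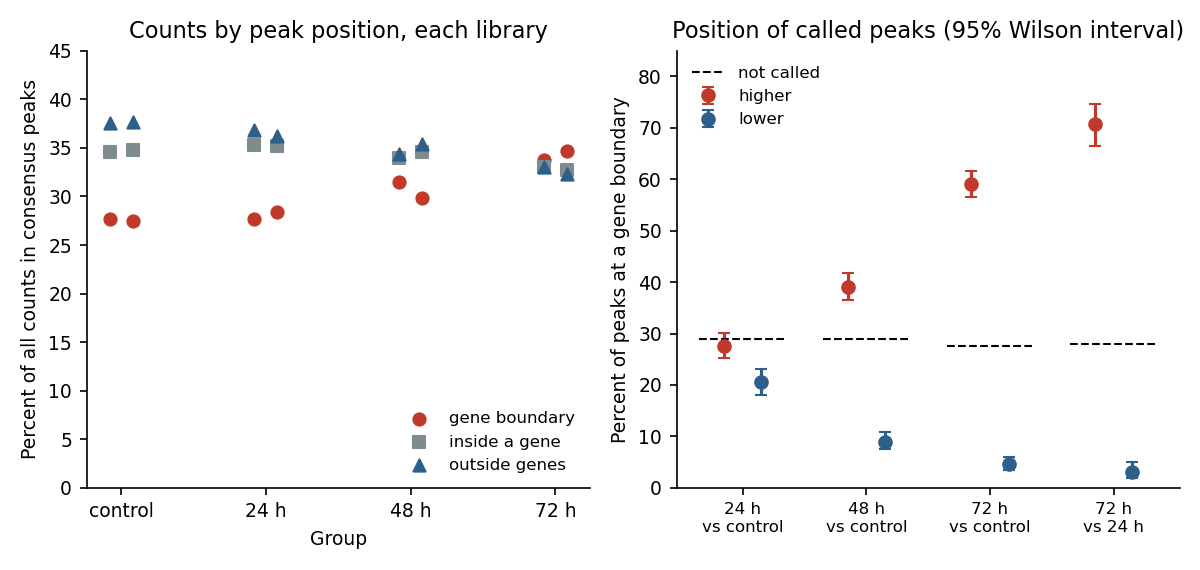
Left, percent of all counts in consensus peaks by peak position for each library (points). Right, percent of called peaks at a gene boundary with 95% Wilson intervals, beside uncalled peaks (dashed), where the share among peaks higher than control goes from 27.6% at 24 h to 59.1% at 72 h.

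The peaks with the highest counts included several that rose over the mean of the 3 times. They were a peak on the unplaced contig JH584304.1 at 58802 to 60551 (0.30, SE 0.0863, adjusted p = 0.00976), Lars2 on chromosome 9 at 123461802 to 123462208 (0.54, adjusted p = 8.91e-06), a peak inside Gphn on chromosome 12 at 78350882 to 78351171 (0.78, adjusted p = 8.02e-10), a peak inside Jarid2 on chromosome 13 at 44869572 to 44870018 (0.13, adjusted p = 0.570), and a peak near Rimbp3 on chromosome 16 at 17222214 to 17222516 (0.70, adjusted p = 6.15e-08). Without control replicate 2 the contig peak (adjusted p = 0.352) and Lars2 (0.0821) did not pass. The contig peak was also lost in DESeq2 (0.159), with summed pairs (0.0573) and with thinned libraries (0.0648).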

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

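The tests that weigh a pattern here were chosen after the pattern had been seen. A first group of results was taken up because the change from control differed between 24 and 72 h in a direct test of the difference. It takes in 999 peaks, the medians of the ZEB1 corepressors and chromatin list (0.40) and of the ribosomal protein list (0.38), and the shares at gene boundaries of peaks higher (70.7%) and lower (3.16%) at 72 h than at 24 h. Both list medians belong to tests that did not pass with an estimated correlation (adjusted p = 0.121 and 0.144).

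Among named peaks the same test set apart 17. Apart from Vim and Epcam, which were fixed in advance, these were named for large changes against control in the same libraries. Part of their difference between 72 and 24 h can follow from that choice. Those higher at 72 h than at 24 h were Klf16 (1.66), Mir5619 (1.35), Vim (0.79), Tmem63a (0.79) and Ankrd12 (0.65). Klf16 and Mir5619 had fallen at 24 h and at 72 h held 71.7 and 84.7 CPM, and 46.2 and 56.5 CPM, against 63.3 and 74.9, and 46.8 and 58.1, in the controls. Those lower were Plscr5 (-2.31), Ier3 (-1.50), Nrep (-1.47), Epcam (-1.42), Hhat (-1.35), Pecr (-1.03), Mreg (-1.02), Ssh3 (-0.95), Slc6a4 (-0.92), Flacc1 (-0.88), Kif2c (-0.86) and BC107364 (-0.69). Ssh3 and Flacc1 had risen at 24 h, and the others were lower than control at 72 h.

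A second kind was signal in regions that the counts leave out. The peak lists hold 3 merged regions on unplaced contigs without counts. GL456359.1 had a fold over IgG of up to 18.4 and GL456216.1 of up to 12.5, each in all 4 lists, and GL456219.1 had 3.84 in the control list alone.

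The gain of signal at gene boundaries with time in the drug was weighed against depth, scaling and the size of peaks. Unequal counts in the peaks and scaling do not account for it. The share of rises at boundaries was 32.2 points higher at 72 h than at 24 h with libraries thinned to the smallest total. It was 31.2 points higher when scaled on low-count peaks. The thinning kept the peaks as they had been called before it. An effect of depth on which regions were called is therefore not covered. Wider or stronger peaks do not account for the gain. Boundary peaks changed by 0.45 more (SE 0.00908, n = 6029) on the log2 scale than other peaks matched in width and count. This SE comes from resampled peaks and matched draws in these libraries, so it holds no spread between libraries. The order of the groups, with 48 h between 24 and 72 h, is what an effect of time in eribulin would give. Handling of each time on a separate day could give the same, and the labels name no batch. There is a single untreated group, and the labels give it no time. Time in culture can therefore not be told apart from time in the drug. GC content and a rise of unspecific cutting at open promoters remain open.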

How the results depend on the processing

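The tests with summed pairs, thinned libraries and peaks inside member genes were chosen after seeing the data. Of 2020 values for named peaks under other settings 1906 kept direction and call, 112 lost the call, 2 gained it and 0 reversed. These pool unlike settings. Total count scaling, close to the main fit, lost 0 of 131, while DESeq2 lost 41 of 131. Among boundary shares 168 of 178 kept direction and call. DESeq2 called 90, 76, 115, 231 and 5 peaks at 24, 48 and 72 h, over their mean and between 72 and 24 h. Its dispersion, test, scaling and filter differ. At 24 h edgeR called 2349 peaks scaled by total count and 2179 scaled on low-count peaks, against 2341. DESeq2 had 1811 peaks at an unadjusted p below 0.05, before its filter, against 5419 in edgeR. Scaling and filter alone therefore do not account for the gap, and dispersion and test were not told apart. Thinned libraries gave 707, 752, 1416, 1539 and 426 by their construction, an adjusted p of 0.1 gave 3533, 3692, 4063 and, between 72 and 24 h, 1952, and summed pairs gave 657 for the last. With 1 library left out these counts ran from 508 to 2515, 517 to 2553, 713 to 2870, 663 to 3507 and 208 to 1135, where the lone library left in a group was taken to vary like the other groups.

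With a −log10 q of at least 5 the 72 h list held 8135 peaks, control overlaps by 24, 48 and 72 h were 60.1, 66.7 and 47.2%, and overlaps by control 80.3, 76.9 and 83.3%. Under reciprocal overlap of 50% they were 51.2, 48.8 and 40.6%, and 63.3, 63.3 and 61.2%. In DESeq2 the boundary shares turned for falls at 24 h (31.0%) and rises at 48 h (25%), and lost their call for falls at 48 h (20%), falls at 72 h when adjusted over all positions (13.2%, adjusted p = 0.0692, or 0.0461 over boundary shares alone), rises at 72 h (40.3%), and rises (100%) and falls (0%) between 72 and 24 h, where few peaks were called. The share of falls at 24 h with thinned libraries was 26.7%. With 1 library left out the shares among rises ran from 21.7 to 28.8% at 24 h, 32.4 to 41.6% at 48 h, 55.4 to 59.7% at 72 h, 39.1 to 46.1% for the mean and 62.7 to 69.7% between 72 and 24 h, and among falls from 18.8 to 22.8%, 7.88 to 11.2%, 4.74 to 6.05%, 7.43 to 9.25% and 1.29 to 3.37%.

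Of the lists called at 48 h, 72 h, the mean and 72 against 24 h (1, 2, 1 and 2), 0 passed with an estimated correlation. Fry called 0 at 48 h, 8 at 72 h, 8 between 72 and 24 h, and 1 for the mean, which was other cell types, falling (adjusted p = 0.0295), and not mesenchymal (0.0511). With the peaks of a list limited to its boundary peaks but still tested against all peaks, the lists that passed were 2 at 24 h, 0 at 48 h, 5 at 72 h and 8 between 72 and 24 h, where YAP and AP-1 targets (adjusted p = 0.00540) and cytoskeleton and adhesion (0.010) turned from falling to rising, while boundary peaks as a whole had a median of 0.32. Peaks inside member genes left 1 list at 72 h, and thinned libraries 1 between 72 and 24 h. With 1 library left out 0 to 1, 0 to 1, 0 to 4, 0 to 1 and 2 to 3 lists passed. The cause of the other changes was not tested. The replicate block changed no count by 1.5 times. The GC correction, alone or with the block, and the motif search were not run for want of a genome sequence. With a median of 10 to 24 counts per peak, 2-fold changes were found in 37.3% of simulated cases at 24 h.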

Other observations

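The gene classes and the tests that weigh explanations in this part were chosen after results had been seen, while the camera test of the mesenchymal list, DESeq2 and the fits without a library were planned. The clearest loss of ZEB1 signal was at genes for small nuclear RNAs, the RNA parts of the spliceosome and related particles. Of 61 tested peaks within 1 kb of such genes, 34 fell at 24 h, 39 at 48 h and 34 at 72 h. Over the mean of the 3 times 37 (60.7%) fell, where 5.20 would be expected from the share of falls among all tested peaks. Of other peaks 8.38% fell (Fisher's exact adjusted p = 2.27e-23 over 60 tests). In these comparisons with control 0 of the 61 rose. Examples over the mean were Rnu2-10 (-1.39), Rnu1b6 (-1.34), Rnu11 (-1.25), Rnu5g (-0.93), Rnu1a1 (-0.92) and Rnu12 (-0.80). The loss was not general, since Rnu7 changed by -0.36 and Rn7sk by 0.10 (SE 0.253, adjusted p = 0.832) without passing.

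Histone genes, which are transcribed mainly in the S phase of the cell cycle, moved the same way. Of 48 peaks within 1 kb of them 18 fell at 24 h, 20 at 48 h, 11 at 72 h and 21 over the mean of the 3 times, where 4.09 would be expected (Fisher's exact adjusted p = 6.30e-10), and 0 rose. The peak shared by H4c18 and H2ac24 changed by -1.05 (adjusted p = 1.04e-10) and that shared by H2ac15 and H2bc15, on chromosome 13 at 21752978 to 21754913, by -0.92 (adjusted p = 9.92e-09). Zinc finger genes of the Zfp family rose more often than others at 72 h, with 30 of 240 peaks (12.5% against 6.78%, adjusted p = 0.00873), but not when set against other boundary peaks (17.1% of 164 against 14.1%, adjusted p = 0.624), so an effect beyond position is not shown. Peaks near transfer RNA genes fell at 24 h in 8 of 57 cases (adjusted p = 0.0188) but not over the mean (adjusted p = 0.262). Long noncoding RNA genes were higher at 72 h than at 24 h at 102 peaks (3.16% against 2.17%, adjusted p = 0.00503), and small nucleolar RNA genes did not pass in any comparison.

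The fall at histone and small nuclear RNA genes could come from changed copy number, from the size of the peaks or from scaling. Other peaks up to 200 kb away changed by -0.0131 (SE 0.0337, n = 300) against -0.56 for these peaks (n = 109), so a lost stretch of chromosome does not account for it. That SE comes from resampling the flanking peaks and holds no spread between libraries. In 1000 draws of other peaks matched in width and count at most 21.1% fell, against 53.2% here, and 54 of the 58 calls remained under the scaling that kept fewest. DESeq2 called 37 of the peaks lower and 0 higher, and 96 of 109 (88.1%) lay below 0. An effect of eribulin on these cells is not tested by these values, and handling of the groups and reads shared by near-identical gene copies also remain open.

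The fall at mesenchymal genes may also follow from where their peaks lie or from a few genes with many peaks. Among peaks away from gene boundaries the list still fell, with camera p = 0.00804 (n = 95 peaks), which did not pass when adjusted over the lists (adjusted p = 0.113). Its boundary peaks as a set were lower than other boundary peaks with adjusted p = 0.00302, so position alone does not account for the fall under the preset correlation. The median over its 36 genes lay at percentile 2.4 of 10000 matched sets of genes, and the median over its peaks at percentile 0 of 10000 sets matched in width and count. A response of these genes to the drug remains possible, but the call rests on a preset correlation and was lost without control replicate 2. It was kept without control replicate 1. Control replicate 2 holds more counts (672582 against 372896), so the loss does not by itself single that library out.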
